A study of Mus musculus with 10 samples.

How the data were processed

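Total RNA from the midbrain of male DBA/1 mice was reverse transcribed, labelled with Cy3 or Cy5 and hybridised to 2-colour mouse oligonucleotide arrays printed in house, per the labels' protocols. Every array carried RNA of collagen-injected mice in one channel and RNA of control mice in the other. The 10 arrays form 5 dye-swap pairs: on 1 array of a pair the collagen RNA was in Cy5, on the other in Cy3. The labels number the pairs 1, 2 or 3, after the 3 biological replicates that the series description states. Replicates 1 and 2 have 2 pairs each and replicate 3 has 1 pair. Arrays that share a number were taken as repeat hybridisations of the same 2 RNAs, so n = 3, except in alternatives fitted on single arrays or on pairs. How many animals went into each RNA is not given in the sources used here.

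The scanner files hold, per the file headers, spot intensities already corrected for background in channels A and B, together with the spot background intensities and a flag per channel. Per the file headers they also give a saturation factor, read here as the fraction of a spot's pixels below saturation. The deposited intensities were not normalised between channels or arrays, and the software that quantified them is not given in the sources used here. There are 29 such files for the 10 arrays. The files of one array are repeat scans of rising brightness, whose log ratios correlated at 0.526 to 0.927 across probes within an array. One array of replicate 2 has 2 scans and the others have 3. The authors' processed value table of the same arrays holds a score per probe and array, with log base and scaling unstated. Its columns have medians between -0.00862 and 0.00332, so they are centred near 0. Set against the scanner files, each column correlated at 0.67 to 0.835 in size with the log ratio of channel B over A. The correlation was positive where the collagen RNA was in Cy5 and negative where it was in Cy3, on all 10 arrays, so the columns turn with the dye orientation relative to the channels. Its spread was 0.283 to 0.533 of that of the log2 ratios, and its unit and direction stay unknown. It served only as an alternative, read there as collagen over control.

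Spots were matched to probe numbers in the order of the printing blocks, then of row and column within the block. Read by rows of the whole slide, the value table correlated with the scanner ratios at no more than 0.0966. Which channel letter is which dye is not stated in the files. Channel A was taken as Cy3, the label of channel 1, and B as Cy5. This direction rests on the order of the labels and is likely rather than stated. The value table turns with the dyes under either choice, and its own direction is unstated, so it does not settle this. With A as Cy5, every sign and every count of higher or lower would turn. The letters were taken to follow the dye and not the RNA, and the closing sections give the other reading. Per scan, 1615 to 4422 spots had a signal in channel A alone and 0 to 169 in B alone, so whether a probe was absent for one RNA was not judged. The background of channel A was above that of B in 29 of 29 scans, over both dye orientations.

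A spot was used where both channels had an intensity over 0 and no X, Y or Z flag. Its log2 ratio was normalised within each scan by loess on brightness (limma 3.58.1 in R 4.3.3, span 0.3, 4 iterations). Ratios were averaged over the scans of an array and turned to collagen over control. They were then averaged over the 2 arrays of a pair, both being required, and over the pairs of a replicate. A probe was tested where all 3 replicates had a value. The design chosen before the data were examined had foreseen a normexp background correction with offset 50. Because the deposited intensities were already corrected, they were used as they stand, and normexp became an alternative. Plain subtraction, also foreseen as an alternative, is the state of the deposited values and was not run again.

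Of the 10080 probes, 9066 have 1 gene symbol in the platform table, 12 have several and 1002 are unnamed here. For 8977 probes the symbol was updated through the gene identifier. No probe with several symbols was named. Per replicate 7353, 6969 and 4677 probes were measured, and 4139 in all 3. Of the 3738 genes among these, 73 had over 1 tested probe, and the brightest probe stood for the gene in gene lists. None of the 30 genes named by rule had a further tested probe.

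The mean log2 ratio of the 3 replicates was tested against 0 with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). Beside it stands a count of probes with a mean over 0.5 in size and the same sign in all 3 replicates. Gene lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. The dye effect was tested in the same way on the ratio of channel B over A. The 27 gene lists, the tests and most alternatives were chosen before the data were examined. The rule for named genes took up to 10 per direction, first among probes past the adjusted threshold by size, then by unadjusted p among probes with the same sign and a mean over 0.5, given as values. It added 2 genes with the smallest p from each immune, pain or transmitter list, and 4 from any list that passed. Predicted or clone names were passed over, which left out 1 probe.

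The pairing rests on the labels. On the 1830 probes measured on all arrays, turned ratios of arrays of opposite orientation were compared, less the mean of each orientation. Within a dye-swap pair they correlated at -0.417 to -0.101. If the letters follow the dye, the arrays of a pair thus shared a deviation of the channels rather than of the RNAs. The 4 comparisons of same-numbered arrays of different pairs gave 0.106 to 0.215. The 16 of arrays with different numbers had a mean of 0.0462 and ranged from -0.248 to 0.342, with 4 above 0.106. Because the mean of each orientation was taken off, negative values within pairs push all other comparisons up. A positive value alone therefore shows no agreement. Alternatives changed the background correction, the normalisation within and between arrays, the filter on dim probes and the scans used. Others changed the replicates, the fit (array level with a dye term, with and without the replicate number as a block, array weights, prior) and the list test. In some alternatives the lists were tested with limma's cameraPR on the moderated t values, as z-scores, which takes no block. These were the fits on single arrays, on pairs, on probes in at least 2 replicates and with the trended prior. The closing section gives the effect of all alternatives.

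The steps were tested on simulated data made from the real scans, with each pair's ratio given a random sign per probe and 200 of the 4139 probes changed by a known amount. Of changes of 0.5, 1 and 2 on the log2 scale, 42.4%, 94.0% and 100% were called, with 1 false call. Fewer changed genes would be harder to call, since the adjustment depends on their number. The change put in was the same in every pair. A response that varied more between replicates than the real ratios do would also be harder to call. The median intensity of used spots was 0.681 to 2.66 times the local background in the single scans.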

Results

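Gene expression in the midbrain was compared between DBA/1 mice with collagen-induced arthritis and control mice on 10 arrays, each of which held both RNAs. DBA/1 is an inbred strain that develops arthritis after immunisation with type II collagen. The mice were males of 8 weeks. The arthritic group was injected into the skin with 100 ul of collagen mixed with 100 ul of complete Freund's adjuvant, and the controls with 200 ul of the adjuvant alone. Both groups were given LPS, a bacterial endotoxin, at day 24, so the controls were not untreated mice. The time of death is labelled as 31, with an unclear unit. On the 10 arrays, 4496 to 8425 of the 10080 probes gave a ratio, and 4139 probes, for 3738 named genes, were measured in all 3 replicates. All ratios below are log2 collagen over control, and a negative value means less RNA in the arthritic mice. This direction is likely rather than stated: it takes channel A of the scanner files as Cy3, after the order of the labels, and with A as Cy5 every sign and count of higher or lower would turn. If the letters instead followed the RNA, with A as control and B as collagen on every array, 55 probes would pass the test. The closing sections weigh that reading.

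The first question was which genes the arthritic midbrain expressed at another level. No gene passed the test. The lowest unadjusted p belonged to Kdm5d, a histone demethylase gene of the Y chromosome, with -0.63 ± 0.19 (SD, n = 3). Id2, an inhibitor of basic helix-loop-helix transcription factors, stood at -0.51 ± 0.24 and the transcription factor gene Mef2c at -0.64 ± 0.46. Hcn2, a channel gene of the pacemaker current in neurons, stood at -0.55 ± 0.49. On the other side, Tsr3, which acts in ribosome maturation, stood at 0.51 ± 0.43 and the adhesion protein gene Mdga1 at 0.59 ± 0.51.

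Of 4139 probes, limma called 0 at an adjusted p under 0.05. The smallest adjusted p was 0.827, shared by Kdm5d and by every other gene named in the previous paragraph. At an unadjusted p under 0.05 there were 163 probes, 50 higher and 113 lower, where 207 would be found by chance. The tested probes as a whole leaned lower, with a median ratio of -0.025. Of the 1230 with the same sign in all replicates, 369 were higher and 861 lower, a similar split. An intensity-dependent Z-score over 2 in all replicates also gave 0 probes. The 95% interval of the ratio lay within a 2-fold change for 4111 probes (99.3%) and within 1.5-fold for 3857 (93.2%), each taken on its own.

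A mean ratio over 0.5 in size with the same sign in all 3 replicates was found for 13 probes, 4 higher and 9 lower, none of them past the test. Simulated data with no change put in gave 10 such probes. Other processing gave 2 (without background correction) to 93 (with median centring) at the same bound, with the arrays turned by the dyes. They include 12 named genes and 1 clone name. Beyond the 6 genes above, the connexin gene Gjc3, expressed by myelinating glia, stood at -0.88 ± 0.85. Ppp2r1b, a scaffold subunit gene of protein phosphatase 2A, stood at -0.73 ± 0.99, the lipid phosphatase gene Plpp1 at -0.57 ± 0.87 and Plxdc1 at -0.56 ± 0.50. Lrig3, a membrane protein gene with leucine-rich repeats, stood at 0.63 ± 0.99 and Flywch2 at 0.54 ± 0.79. Single replicates made up most of several means. Replicate 1 gave -1.86 for Gjc3, -1.87 for Ppp2r1b and -1.57 for Plpp1, and replicate 3 gave 1.77 for Lrig3, 1.46 for Flywch2 and 1.19 for Mdga1. Kdm5d, by contrast, lay between -0.82 and -0.45 in the 3 replicates.

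**Figure D1:**
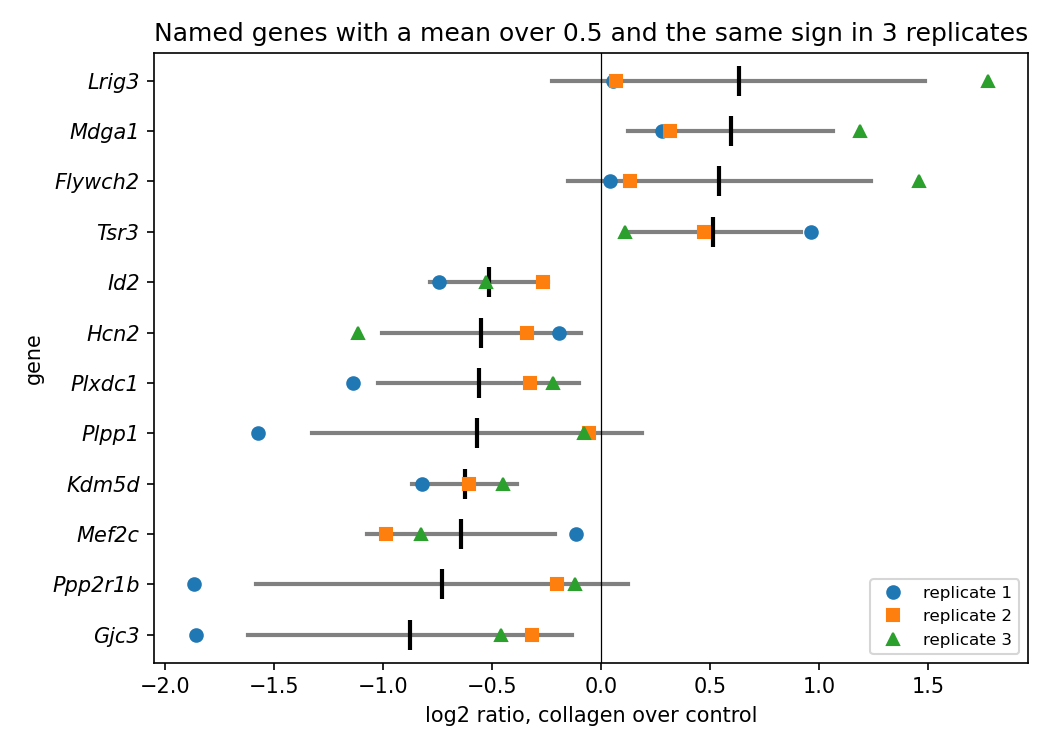
Log2 ratio collagen over control (x axis) of the 12 named genes (y axis) with a mean over 0.5 in size and the same sign in 3 replicates. Points are replicates, the black tick is the mean and the grey bar its 95% interval from limma; Kdm5d spans -0.82 to -0.45, while Gjc3 reaches -1.86 in replicate 1 and Lrig3 reaches 1.77 in replicate 3.

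Among genes of transmission and pain no list passed camera, and no member passed over all genes or adjusted over the list alone. Of 8 measured genes of dopamine neurons, 3 were higher and 5 lower. Their leading members were Ddc, the enzyme that makes dopamine from L-DOPA, at 0.18 ± 0.15, and Th, the rate-limiting enzyme of dopamine synthesis, at 0.35 ± 0.47 (SD, n = 3). The list's median was -0.03, its mean 0.04 and its test upward (camera adjusted p = 0.535), so these differ in sign. The upward side rested on replicate 3, where Th stood at 0.88, against 0.03 and 0.13 in the others; without it the test turned downward (adjusted p = 0.881). Of 6 GABA genes, 5 were lower. Slc32a1, the transporter that loads GABA into vesicles, stood at -0.27 ± 0.03, with -0.25 to -0.30 in the replicates, and Gad2, a GABA-synthesising enzyme, at 0.11 ± 0.08. Adjusted over the list alone, Slc32a1 reached an adjusted p of 0.0693, and over all genes 0.827. The list as a whole had a camera adjusted p of 0.532. With limma's fry for changes in either direction, which compares it with no other genes, the adjusted p was 0.0453. Of 13 measured opioid, peptide and pain genes, 5 were higher and 8 lower (camera adjusted p = 0.598). Cartpt, a neuropeptide precursor, stood at -0.21 ± 0.19 and the cholecystokinin receptor gene Cckbr at -0.17 ± 0.20. Serotonin genes with a value were Gata3, Htr2c and the transporter gene Slc6a4, and glutamate genes were the receptor subunits Gria4 and Gria1, too few for a list test. Gata3 stood at -0.04 ± 0.03, Htr2c at 0.03 ± 0.08, Gria4 at 0.10 ± 0.03 and Gria1 at -0.03 ± 0.17.

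Immune genes were compared because collagen arthritis is an inflammatory disease of the joints. Of 7 measured cytokine and NF-kB genes, 4 were higher and 3 lower (camera adjusted p = 0.45). Lcn2, an acute-phase protein gene that inflammation induces, stood at 0.38 ± 0.96, with 1.49 in replicate 2 and -0.14 and -0.19 in the others. Il18 stood at 0.09 ± 0.16 and Il1b, the interleukin-1 beta gene, at 0.01 with a 95% interval of -0.19 to 0.20. Of the interferon genes, Ifit3 stood at 0.35 ± 0.34 and Isg15 at 0.08 ± 0.21. Of the leukocyte genes, the B-cell receptor component Cd79b stood at 0.29 ± 0.22, the T-cell marker Cd5 at -0.13 ± 0.05 and S100a8, abundant in neutrophils, at 0.39 with an interval of -0.15 to 0.92. Of 7 microglia and macrophage genes, 4 were higher and 3 lower (camera adjusted p = 0.821). The complement gene C1qc stood at -0.12 ± 0.09, and Laptm5, a lysosomal protein gene of leukocytes, at -0.15 ± 0.29. The median of the microglia list was 0.01, while its mean was -0.03 and its test downward. No gene of the complement and acute-phase list was measured in all replicates, although 9 have a probe. Of genes with a probe, 7 of 24 cytokine and NF-kB genes and 2 of 11 interferon and MHC genes were measured. For leukocytes it was 3 of 12 and for microglia and macrophages 7 of 12, so most immune genes were not judged. Of 51 genes in the immune, pain and transmitter lists, the 95% interval lay within a 2-fold change for 50.

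Genes of the neuronal cytoskeleton had the lowest median among lists with at least 5 measured genes. Of 9 measured, 8 were lower and 1 higher, with a median of -0.11. Map1b, a microtubule-associated protein, stood at -0.25 and Ina, a neurofilament protein, at -0.27. The list did not pass (camera adjusted p = 0.145, and adjusted p = 0.811 with an estimated correlation), and the medians of the replicates, -0.05, -0.04 and -0.23, rested on replicate 3. With a trended robust prior its adjusted p was 0.0337, without background correction 0.0308 and without replicate 3 it was 0.602, within a range of 0.0308 to 0.9 over all alternatives. Of 10 synaptic vesicle genes, 8 were lower, among them the synapsin gene Syn1 at -0.29 (camera adjusted p = 0.416 for the list). Of 9 oligodendrocyte and myelin genes, 6 were lower, and of 5 astrocyte genes, 4 were lower, both with a camera adjusted p of 0.45. Of 38 genes of oxidative phosphorylation, 30 were lower, and of 31 ribosomal protein genes, 25 were lower. Their medians of -0.04 lie close to the median of -0.025 over all tested probes, and neither list passed (camera adjusted p = 0.45 and 0.453). Both passed without replicate 3, at an adjusted p of 0.029, and without background correction, at 0.00512, with a preset correlation. With all replicates, both had an adjusted p = 0.811 with an estimated correlation. Over all alternatives they ranged from 5.67e-05 to 0.919 and from 0.000316 to 0.94. Without replicate 2 the test of oxidative phosphorylation turned upward (adjusted p = 0.841). The 0.94 of ribosomal proteins came from the authors' value table, whose direction is unknown. With channel A taken as control and B as collagen on every array, both tests were upward (camera adjusted p = 0.268 and 0.238). Of 12 genes of heat shock and the unfolded protein response, 10 were lower, with the chaperone gene Hsph1 at -0.25 (camera adjusted p = 0.45). Of 14 antioxidant genes, 8 were higher (camera adjusted p = 0.487), and of 6 genes of cholesterol synthesis, 4 were higher (0.45).

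Markers of neighbouring tissue and blood were few. All 4 measured cerebellar genes were lower, led by the transcription factor gene Neurod1 at -0.38. Its adjusted p was 0.0694 over the list alone, and 4 genes were too few for a list test. Of 5 forebrain genes, 3 were higher and 2 lower, with a median of 0.03, a mean of -0.06 and a downward test (camera adjusted p = 0.952). Igf2 of the choroid plexus list stood at -0.25 and Kl at 0.14. The hypothalamic peptide genes Pmch and Oxt stood at 0.06 and 0.03, and the endothelial gene Eng at 0.02. No red-cell gene was measured in all replicates. Among glucocorticoid-response and immediate early genes, with 4 measured each, Dusp1 stood at -0.10, Mt1 at 0.08 and Fos at -0.01. In all, 0 of 15 tested lists and 0 of 207 measured list genes passed.

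**Figure D2:**
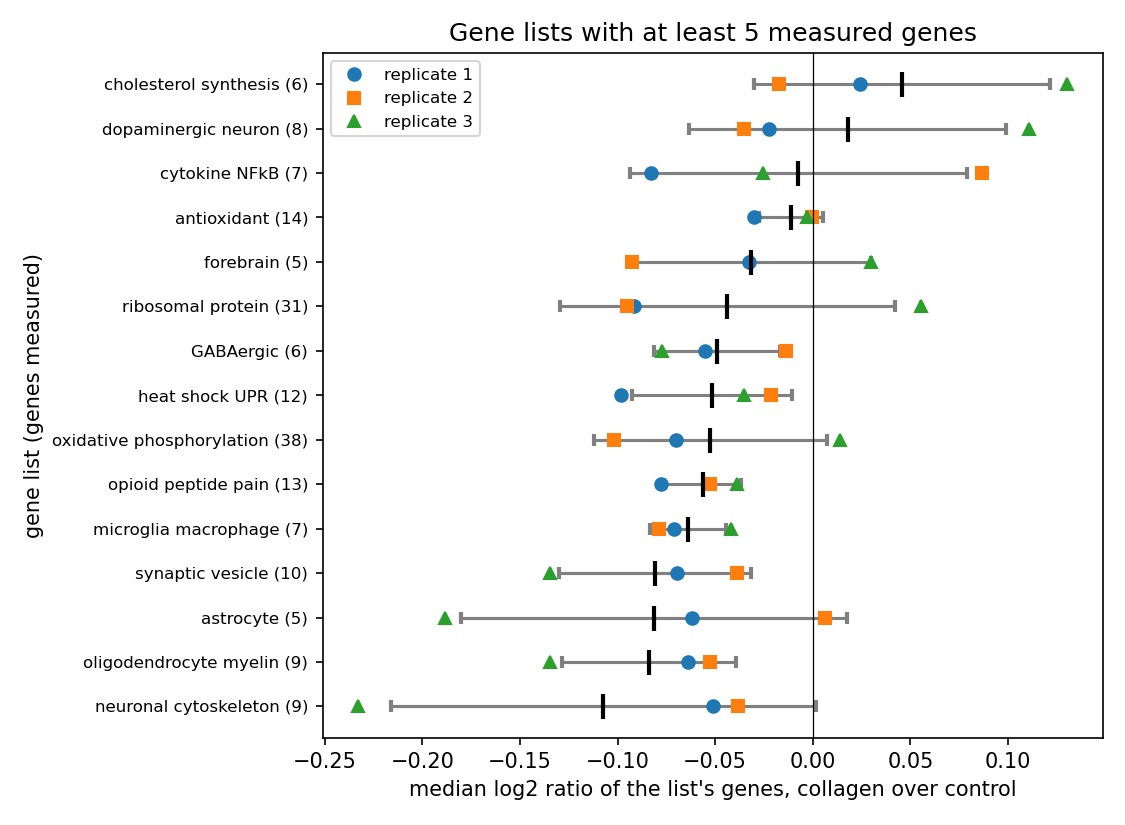
Median log2 ratio collagen over control (x axis) of the genes of each list with at least 5 measured genes (y axis, number of genes in brackets). Points are replicates, the black tick is their mean and the bar is 1 SD (n = 3); the neuronal cytoskeleton list lies lowest, with medians of -0.05, -0.04 and -0.23.

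Genes also differed between channels A and B over both dye orientations. This is called a dye effect here, on the reading that the channel letters follow the dye. Of 4139 probes, 55 passed the test for a dye effect, and all 55 were brighter in channel A. Their log2 ratios of channel B over A lay between -2.55 and -0.63. If the letters followed the RNA, these 55 would be the treatment calls. The lowest ratio was that of the keratin gene Krt14, with the chondroitin sulphotransferase gene Chst13 at -2.41 and Kdm5d at -2.40. With the direction turned to collagen over control, Krt14 stood at -0.09 and Chst13 at -0.06. Across all probes the SD of the dye effect was 0.28, against 0.133 for the treatment ratio. In an array-level fit with the replicate number as a block, 342 probes passed for the dye and 0 for the treatment. With normexp correction or with median centring, 0 probes passed for the dye.

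The replicates were also compared with each other over the same genes. Across the 4139 probes, the treatment ratios of replicates 1 and 2 correlated at 0.11, those of 1 and 3 at 0.0293 and those of 2 and 3 at 0.0054. These are correlations across genes, which are not independent replicates. The repeat dye-swap pairs of replicate 1 correlated at 0.0297 and those of replicate 2 at 0.0747, while pairs of different replicates ranged from -0.0583 to 0.063. Before turning, the channel ratios of the 2 arrays of a pair correlated at 0.337 to 0.71. For comparison, the largest ratios of named genes such as Gjc3 or Lrig3 came from 1 replicate each.

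**Figure D3:**
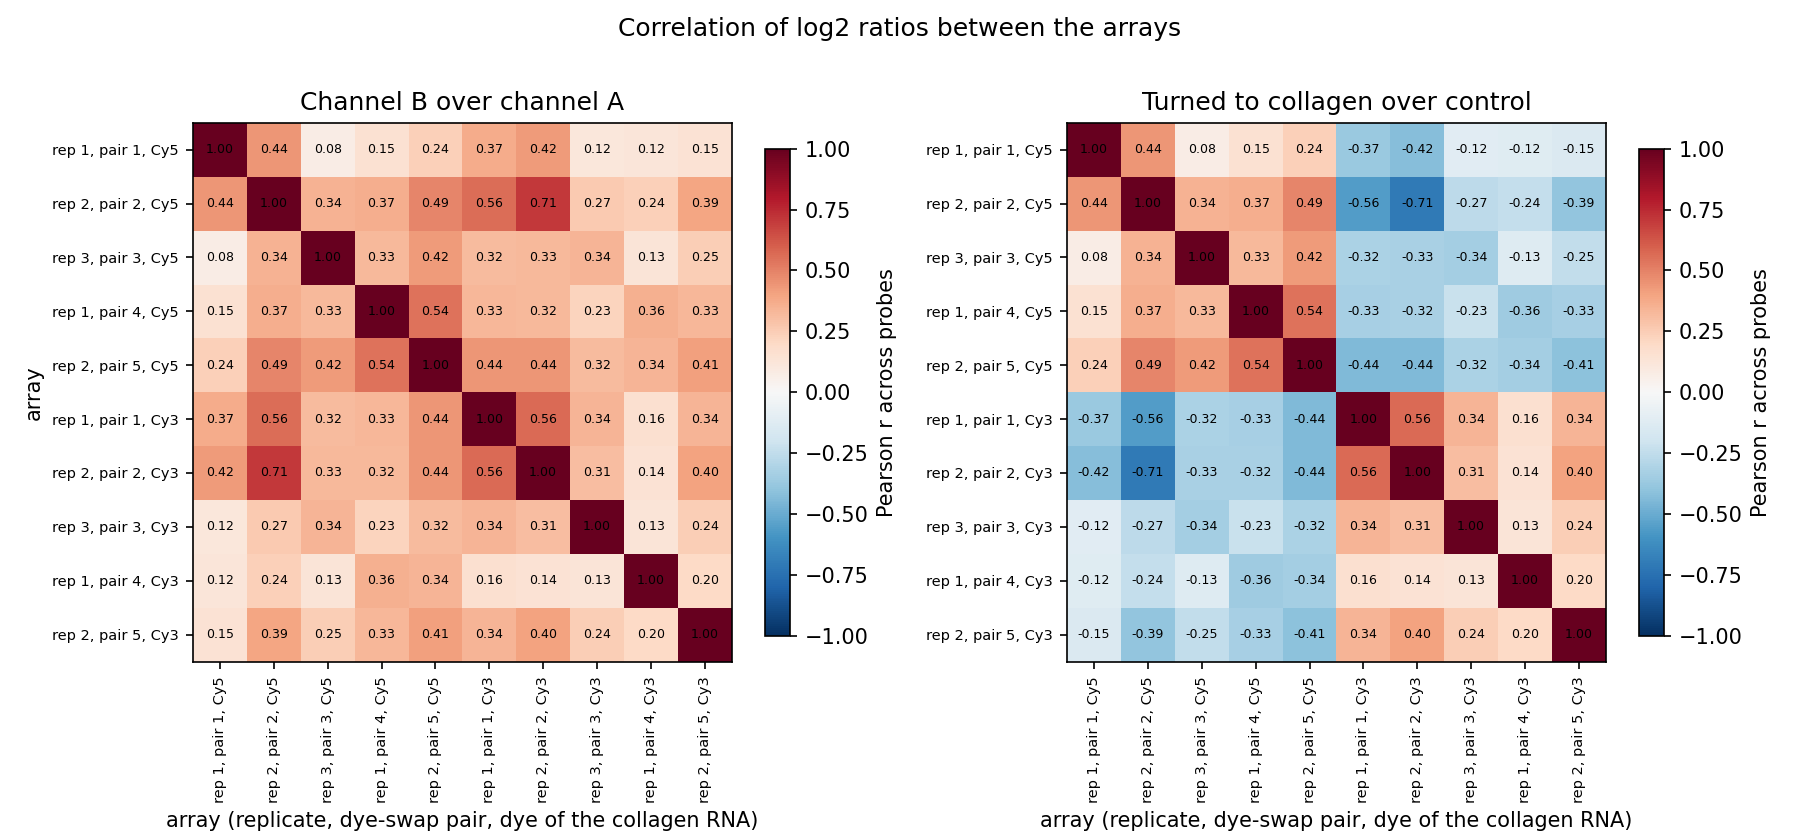
Pearson correlation across probes between the 10 arrays (both axes; replicate, dye-swap pair, dye of the collagen RNA), for channel B over A (left) and after turning to collagen over control (right). On the left all values are positive, from 0.08 to 0.71; on the right, arrays of opposite orientation are negative, down to -0.71.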

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

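A screen of 8 technical measures over the 5 arrays of each dye orientation marked 2 of 16 sets in which a single array lay far from the rest, and chance marks about 1 in 20. On the array of replicate 2 with collagen RNA in Cy5 and 2 scans, the mean signal over background was 2.41, where the next array had 1.5. On the array of replicate 3 with collagen RNA in Cy3, the median of the authors' value table was -0.00862, where the next array had -4.37e-05. Neither array was marked for the number of probes measured. The array of replicate 2 did have the fewest of its orientation, 4496, where the next had 5742.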

How the results depend on the processing

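Alternatives with fixed channel letters, probes in at least 2 replicates, a left-out pair, named probes and recentring were chosen after the data were seen. Normexp had been foreseen for the main fit and was made an alternative once the data were seen. The count of 0 changed probes held in 26 of 27 alternatives. The exception takes channel A as control and B as collagen on every array, and gave 55 changed probes, 192 consistent probes and a mean replicate correlation of 0.499. Among the 26 is the authors' value table, read as collagen over control although its direction is unstated. Read as a ratio of the dyes and turned, it gave 59 probes in the same test, so its 0 depends on that choice. The replicate number as a block left 0 changed probes (consensus correlation -0.0926) but gave 342 dye calls, and the fit without the block 392; the block changed no other call.

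The 13 consistent probes became 2 without background correction, 93 with median centring, 63 with normexp, 4 with print-tip loess, 8 without the dimmest 33.3% of probes, 7 without the dimmer 50%, 7 with the third scan alone, 6 without saturated spots, 20 with the first pair of each replicate, 56 with probes in at least 2 replicates and 0 at a mean over 1. For the array with 2 scans, its second scan stood in for the third. Leaving out a replicate gave 24 to 50 (26 without replicate 1, 50 without replicate 2), where only 2 signs need to agree. List calls went from 0 to 3 without background correction, 2 with array weights, 1 with a trended robust prior, and lay at 0 to 2 with a replicate left out, the 2 without replicate 3. Dye calls were 83 with scaling between arrays, 13 and 8 with the first or second scan alone, 96 with 5 pairs, 775 with array weights, 90 with the trended prior, 33 without the first pair of replicate 1, 0 with median centring and 0 with normexp, and 28 (without replicate 2) to 218 (without replicate 1) with a replicate left out. The mean replicate correlation of 0.0481 ranged from 0.0054 to 0.11 with a replicate left out, 0.11 being without replicate 3. Except for the numbers of probes, scans or replicates, the cause was not tested.

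Of 676 values of named genes under alternatives, 615 moved by under 1 SD and 15 changed sign outside the fixed channel letters, none of them among the 12 genes over 0.5. Those 12 were picked for the same sign in all replicates. Leaving out a replicate, filtering probes or changing the prior could therefore not turn their sign. With the fixed channel letters, 8 values of these 12 genes did change sign. For every named gene, filtering probes or changing the prior leaves the mean as it is. Leaving out a replicate always moves it by less than 1 SD. Part of the 615 was therefore fixed in advance. The authors' value table was not part of this count.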

Other observations

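The tests of the channel letters, of the noise of hybridisations and of Kdm5d were chosen after the results were seen, as were the counts of sign patterns for changed probes and consistent probes.

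With limma's fry, which asks whether the genes of a list change in either direction, the 6 GABA genes had an adjusted p of 0.0453. Its directional form gave an adjusted p of 0.511, and neither form compares the list with other genes. The member with the smallest p was Slc32a1, the vesicular GABA transporter, at -0.27 ± 0.03 (SD, n = 3). Gad1 and Gad2, both enzymes of GABA synthesis, stood at -0.05 and 0.11, and the parvalbumin gene Pvalb at -0.04. Genes of energy supply and translation did not pass as lists in the main fit (camera adjusted p = 0.45 and 0.453), and no member passed. With array weights, the lists of oxidative phosphorylation and ribosomal proteins had adjusted p values of 5.67e-05 and 0.000316, against up to 0.919 and 0.94 under other alternatives. Those with array weights came from a fit on 10 arrays without a replicate block, with limma's cameraPR on moderated t values at the preset correlation. An array-level fit with the replicate number as a block gave 0.205 for both, and the main fit gave both an adjusted p = 0.811 with an estimated correlation. In replicate 3 their medians were 0.01 and 0.06, against -0.07 to -0.10 in the others.

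The ratio of channel B over A kept its sign in arrays with swapped dyes, for Krt14 and Chst13 among 55 probes. If the channel letters followed the RNA, these 55 would be treatment effects, and a background set by the dye would be higher in A on one orientation and in B on the other. It was higher in A on 29 of 29 scans, which argues against that reading unless the RNA set the background. Dye bias of single probes stays open. Of the 55, 12.7% had an unadjusted treatment p under 0.05, against 3.94% of all tested probes, but a constant channel ratio cancels when arrays are turned, so this share decides nothing. No biological explanation was tested.

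Treatment ratios barely correlated between replicates, on average at 0.0481. Incomplete cancellation of dye bias stays open. Leaving out the probes with the largest dye effect moved the mean by 0.00405. Without a treatment signal shared by the replicates, the mean would stay low either way, so this does not decide. Across the tested probes, the sizes of the treatment ratio and of the dye effect had a rank correlation of 0.16. Noise of single hybridisations is a candidate explanation, since pairs sharing a replicate number correlated only 0.0288 better than other pairs. Wrong replicate numbers would look the same and stay open: single arrays of the same number from different pairs correlated at 0.106 to 0.215, above the mean of 0.0462 for other arrays but within their range. Differences between animals in their response to collagen were not tested directly. As the whole cause, such differences would leave repeat pairs of the same RNAs in agreement, yet those pairs correlated at only 0.0297 and 0.0747. If the replicate numbers are right, this argues against such differences as the whole cause. As a part of the cause they stay open.

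Kdm5d had both a treatment ratio of -0.63 and a dye effect of -2.40. A constant dye effect cancels in the mean of both orientations, but a remnant that does not cancel stays open as a cause. The 7 other probes with a dye effect over 2 in size had a median treatment ratio of -0.18 (SD 0.0959) and lay between -0.358 and -0.0578, while the replicates of Kdm5d lay between -0.822 and -0.45. Those 7 were all lower in collagen, as were 38 of the 55 probes called for a dye effect. Because Kdm5d was picked for the lowest p of all tested probes, its place beyond the 7 does not decide the question. Kdm5d kept 26% of its dye effect, against a median of 7.94% (SD 15.4%) for the other 54 called probes, of which 7 kept a larger share, so this share alone does not set it apart. An earlier test on the median ratio of those 54, -0.105, fell between its bounds of -0.2 and -0.1 and took no account of the size of each dye effect. Chance stays open, since Kdm5d did not pass, as does a response to collagen, which was not tested.

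With 3 replicates only 4 sign patterns exist, too few for a share under 0.05. For changed probes all 4 patterns gave as many as the real 0, and the highest of the others was 0. For consistent probes 2 patterns reached the real 13, and the highest of the others was 13. For gene lists all 4 reached the real 0, and the highest of the others was 2. For the dye effect only the real pattern, 1 of 4, reached 55, and the highest of the others was 0.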
